A study of Mus musculus with 9 samples.

How the data were processed

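RNA from Ly6C low, MHC class II positive macrophages sorted from the colon lamina propria of 6-week-old WT, p47phox-/- and gp91phox-/- mice was sequenced as paired-end libraries on a NovaSeq, 3 libraries per genotype and 9 in all. Per the labels' protocols, RNA was extracted with an RNeasy kit. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.19, reads were trimmed with Cutadapt and aligned to mm10 with STAR 2.5.2b, reads on genes were counted with featureCounts, and DESeq2 was used. The deposited values are normalized counts, a signal in which the authors divided each library's reads by a size factor. In each library the values were whole multiples of a step, to which whole reads were recovered in 100% of values (tolerance 0.01), and the size factors read from these steps were 1.05 to 1.66. They exceeded those recomputed with DESeq2 from the 9 libraries by 1.16 to 1.21 times, a nearly common factor. Which strand and which gene annotation were counted is not given in the sources used here. Recovered reads were 31141107 to 52797368 per library. Whether each library came from a separate animal is not stated in the labels, so p-values measure the spread between these samples, which may be partly technical.

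The table held 42454 genes, of which 36134 matched the GRCm38.p6 gene table by symbol. All genes on chromosomes X (1362) and Y (190) and the mitochondrial genome (24) were listed at 0 in every library, so Cybb, Xist and Y-linked genes could not be read, and the sex of the animals was not checked. Another 13 symbols had been turned into dates, and 2346 entries with a numbered suffix were listed at 0. No pair of libraries was near-identical.

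Values were transformed to log2(normalized count + 1). Genes with at least 10 normalized counts in at least 3 libraries (14404) were tested in limma 3.58.1 under R 4.3.3, with 1 fit of the 3 groups, an empirical Bayes mean-variance trend and Benjamini-Hochberg adjustment, and were called at an adjusted p under 0.05. The comparisons were p47phox-/- versus WT, gp91phox-/- versus WT, gp91phox-/- versus p47phox-/- (which is also the test of a difference between the knockouts' effects) and the mean of both knockouts versus WT. Comparisons, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Except where stated, numbers in parentheses after gene names in the report are log2 fold changes. Spreads are SD over 3 libraries. Named genes were the 10 per direction (5 for gp91phox-/- versus p47phox-/-) with the greatest fold change among called genes with a mean of at least 50, without immunoglobulin segments and unnamed genes, besides the targeted genes and members of the lists. The naming rule also required no overlap between the libraries of the groups compared, and left out T cell receptor segments. Some of these results are not reported here, but counts and lists include them.

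There were 29 fixed lists, of which 26 had at least 3 tested members. They covered NADPH oxidase subunits, mature resident gut macrophage genes, monocyte genes, inflammatory genes, interferon-induced genes, alternative activation, MHC class II presentation, phagocytosis and lysosome, TGF-beta and IL-10 signalling, antioxidant genes, oxidative phosphorylation, glycolysis and hypoxia, cholesterol, unfolded protein response, cell cycle, immediate-early genes and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, under which 0 lists were called in any comparison. Fry, which asks whether a list changed at all rather than against other genes, was fixed beside camera. It called 1, 7, 5 and 6 lists in the 4 comparisons in the order above. In p47phox-/- versus WT this was the fibroblast list (fry adjusted p = 0.0391). Shares of members were also adjusted over the list alone. Genes near Ncf1 were compared with others by Fisher's exact test in a window of 10 Mb. The overlap of the knockouts was set against 50 simulated data sets with no effect that shared the WT libraries. Intervals for ratios of low counts are 95% intervals from pooled reads.

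The steps were tested on simulated data with 200 changed genes. Of changes of 2-fold, 54, 47, 52 and 64% were recovered in the 4 comparisons in the order above, and of 4-fold 91, 88, 95 and 91%, with 12, 14, 7 and 14 false calls among 157, 149, 154 and 169. The alternatives were other pseudocounts, filters and scalings, only the groups compared, the replicate number as a block, each library left out, array weights, no trend, and edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads. Added after seeing the data were fits without immunoglobulin segments and the B and plasma cell list, and without p47phox-/- replicates 2 and 3. The genes Cx3cr1, Cd79b and Ighm were singled out after their values were seen.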

Results

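RNA sequencing was performed on macrophages (Ly6C low, MHC class II positive) sorted from the colon lamina propria, the connective tissue layer under the gut epithelium, of 6-week-old mice. The 3 genotypes were wild type (WT), p47phox-/- and gp91phox-/-, with 3 libraries each. Both targeted proteins are subunits of the phagocyte NADPH oxidase, the enzyme complex that makes superoxide. gp91phox, encoded by Cybb, is its membrane-bound catalytic subunit. p47phox, encoded by Ncf1, is the cytosolic subunit that organises assembly. The series title places the comparisons in a study of reactive oxygen species in intestinal macrophage development. The libraries held 31141107 to 52797368 reads assigned to genes. Libraries of the gp91phox-/- group had at least 1 read on 18115 to 18760 genes and WT libraries on 15825 to 17280. In the p47phox-/- group, replicate 1 had reads on 17754 genes, but replicates 2 and 3 on 14323 and 14268 at similar depth. In a principal component analysis, replicates 2 and 3 stood apart from the other 7 libraries and from each other. They lay at opposite ends of the second component (-95.1 and 98.3). The first component (30.1% of the variance) set the gp91phox-/- libraries (65.7 to 75.2) apart from the others (-87.2 to -9.22). The lowest correlation between libraries of a group (Pearson, log2 scale, across genes, which are not independent replicates) was 0.885 in p47phox-/-, 0.951 in WT and 0.977 in gp91phox-/-.

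The targeted gene was examined first. Ncf1 (GRCm38, chromosome 5, 134220053 to 134229628, protein-coding) had a normalized count of 9957 ± 918 in WT (SD, n = 3), 3195 ± 510.4 in p47phox-/- and 13039.5 ± 793 in gp91phox-/-. It was lower in p47phox-/- than in WT by 3.13-fold (log2 fold change -1.65, SE 0.14, adjusted p = 0.000348), and each p47phox-/- library lay below each of the other 6. In gp91phox-/- it was not called against WT (log2 fold change 0.39, adjusted p = 0.118), but was called higher in DESeq2 (adjusted p = 0.0425) and, narrowly, with array weights. Cybb (chromosome X, 9435252 to 9487766) was listed at 0 in all 9 libraries, as were all 1362 genes placed on chromosome X, so the labels of the gp91phox-/- libraries could not be checked on their target. The other measured subunits of the oxidase and its relatives were not called in either knockout against WT (7 tested, 0 adjusted over the list alone, camera adjusted p = 0.531 in p47phox-/- and 0.777 in gp91phox-/-).

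**Figure D1:**
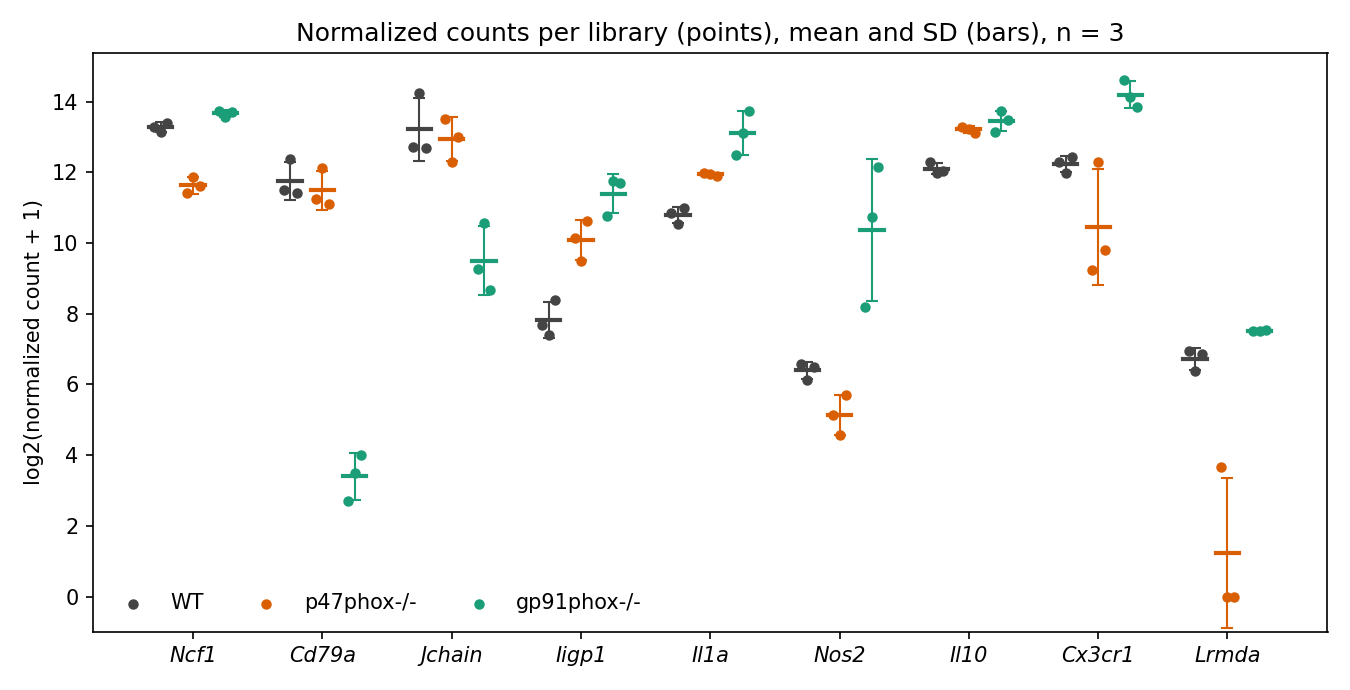
Normalized counts of 9 genes on the scale log2(normalized count + 1) in WT, p47phox-/- and gp91phox-/- libraries; points are libraries, and bars give the mean and SD of 3 libraries. Ncf1 lies lowest in p47phox-/-, the B cell gene Cd79a lies lowest in gp91phox-/-, and Cx3cr1 spans 598 to 5056 within the p47phox-/- group.

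Macrophages of p47phox-/- mice differed from WT in a limited set of genes, with the chemokines Ccl22 and Ccl8 among those that rose and Lcn2 and Saa3 among those that fell. Iigp1, an interferon-inducible GTPase, rose from 236 ± 88.2 to 1143 ± 433 normalized counts (SD, n = 3; log2 fold change 2.26, SE 0.34, adjusted p = 0.00848). The interferon-induced list as a whole was not called in p47phox-/- (1 of 35 rose, 2 higher and 0 lower adjusted over the list alone, median log2 fold change 0.13, camera adjusted p = 0.204). Ccl22, a chemokine that attracts cells bearing CCR4, rose from 414 ± 104 to 1509 ± 155 (log2 fold change 1.89, adjusted p = 0.0149), and the monocyte chemoattractant Ccl8 from 2179 ± 437 to 7701 ± 1363 (log2 fold change 1.82, adjusted p = 0.0074). Lcn2, a siderophore-binding protein, fell from 488 ± 486 to 15.2 ± 6.48 (log2 fold change -4.52, adjusted p = 0.00783), and Saa3, an acute-phase serum amyloid, from 8589 ± 8099 to 470.2 ± 64 (log2 fold change -3.79, adjusted p = 0.0233), both with a WT spread as wide as the WT mean. In all, 162 of 14404 genes tested were called (limma, adjusted p under 0.05), 90 higher and 72 lower. This balance turned to 85 higher and 150 lower without p47phox-/- replicate 1, 45 and 60 without WT replicate 2, 29 and 32 without p47phox-/- replicate 3 and 25 and 27 without a mean-variance trend, and was even with TMM scaling (86 and 86).

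The other genes named by rule in p47phox-/- were of varied function. Higher, with log2 fold changes in parentheses, were Vasn, a binder of TGF-beta (1.84), Sardh, sarcosine dehydrogenase (1.83), the protease inhibitor Serpina3f (1.81), the membrane transporter Slc45a3 (1.81), Tln2, a talin that links integrins to actin (1.73), elastin (Eln, 1.65) and Nrg2, an ErbB receptor ligand (1.62). Lower were Lrmda (-5.51), Ifi208, of the interferon-inducible PYHIN family (-4.25), the ErbB ligand Nrg1 (-2.34), the secreted protease Htra1 (-2.30), Angptl4, an inhibitor of lipoprotein lipase (-2.23), Tmem26 (-2.22), Rundc3b (-2.14) and the chemokine Ccl5 (-2.08). Adjusted p ranged from 0.00351 for Tmem26 to 0.0365 for Eln. Lrmda had 14 reads over the 3 p47phox-/- libraries against 386 in WT, a ratio of 25.4-fold (95% counting interval 15 to 47, which leaves out the spread between libraries). Its normalized counts were 11.8, 0 and 0 in p47phox-/- replicates 1, 2 and 3, and those of Ifi208 4.2, 0 and 0.953. In WT libraries Lrmda was 82.2 to 122.6 and Ifi208 29.8 to 52.1. Replicate 1, which had reads on 17754 genes, thus lay below each WT library for both genes. Replicates 2 and 3 had reads on fewer genes, and whether this lowered their values further was not tested. Genes within 10 Mb of Ncf1 were not called at a higher share than other genes (2 of 212 against 157 of 13896, odds ratio 0.833, 95% interval 0.0994 to 3.1, two-sided Fisher's exact test p = 1), and Eln was 1 of the 2. With 1 library left out, 9 of the 20 named genes stayed called in every case, but each of these 9 lost the call without a mean-variance trend or without p47phox-/- replicates 2 and 3 together (chosen after seeing the data; adjusted p up to 0.208). Ccl22 lost the call without WT replicate 1 or 3, or p47phox-/- replicate 3 (adjusted p = 0.0598 to 0.0745). Vasn lost the call without WT replicate 1, 2 or 3, or p47phox-/- replicate 1, 2 or 3 (adjusted p = 0.0561 to 0.095). Sardh lost the call without WT replicate 1, 2 or 3, or p47phox-/- replicate 1 or 3 (adjusted p = 0.0537 to 0.077). Serpina3f lost the call without WT replicate 1, 2 or 3, or p47phox-/- replicate 3 (adjusted p = 0.0501 to 0.104). Slc45a3 lost the call without WT replicate 1, 2 or 3 (adjusted p = 0.058 to 0.0603). Eln lost the call without WT replicate 1, 2 or 3, or p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 2 (adjusted p = 0.0509 to 0.138). Nrg2 lost the call without WT replicate 1 or 3, or p47phox-/- replicate 3 (adjusted p = 0.058 to 0.0812). Lrmda lost the call without WT replicate 3 (adjusted p = 0.0567). Ifi208 lost the call without WT replicate 2 or 3 (adjusted p = 0.0565 to 0.0726). Saa3 lost the call without WT replicate 1 or 2, or p47phox-/- replicate 1 or 3 (adjusted p = 0.051 to 0.102). Rundc3b lost the call without WT replicate 1, 2 or 3, or gp91phox-/- replicate 1, 2 or 3 (adjusted p = 0.0536 to 0.151).

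Among gene lists fixed before the data were examined, the mature resident gut macrophage genes were called higher in p47phox-/-, and of the 30 tested, 6 rose, 1 fell and 23 were not called (8 higher and 2 lower adjusted over the list alone). The mature macrophage list had a median log2 fold change of 0.28 (camera adjusted p = 0.000338, adjusted p = 0.589 with an estimated correlation), and lost the call without WT replicate 2 (adjusted p = 0.127). Timd4 (1.31) and Folr2 (1.22), surface receptors of long-lived tissue macrophages, and the anti-inflammatory cytokine Il10 (1.11) rose, while Gpnmb, a glycoprotein of lipid-laden macrophages, fell (-1.20). Of the inflammatory cytokines and NF-kB targets, 7 rose, 1 fell and 22 were not called (15 higher and 2 lower adjusted over the list alone). The inflammatory list had a median log2 fold change of 0.40 (camera adjusted p = 6.6e-08, adjusted p = 0.584 with an estimated correlation). The neutrophil chemoattractant Cxcl1 (1.56), the adhesion molecule Icam1 (0.88) and the monocyte chemoattractant Ccl2 (1.43) rose, and Ccl5 fell (-2.08). Gpnmb lost the call in 6 of its alternatives, among them without WT replicate 1 or 2, or p47phox-/- replicate 3 (adjusted p up to 0.285). Icam1 lost the call in 4 of its alternatives, among them without WT replicate 3, or p47phox-/- replicate 3 (adjusted p up to 0.27). Ccl2 lost the call in 6 of its alternatives, among them without WT replicate 2 or 3, or p47phox-/- replicate 3 (adjusted p up to 0.312). Fibroblast and smooth muscle markers were also called higher in these libraries (median log2 fold change 0.88), and whether such cells contributed to these lists was not tested. In the list of alternative activation and repair, the lectins Mgl2 (1.55) and Clec10a (0.98) rose and the angiogenic factor Vegfa fell (-0.74), with 17 of 20 not called (5 higher and 1 lower adjusted over the list alone). The alternative activation list had a median log2 fold change of 0.01 (camera adjusted p = 0.0427, adjusted p = 0.398 with an estimated correlation), and lost the call without WT replicate 1 or 2, or p47phox-/- replicate 2 or 3 (adjusted p = 0.0585 to 0.135) and under quantile normalization (adjusted p = 0.0785). Clec10a lost the call in 4 of its alternatives, among them without WT replicate 3, or p47phox-/- replicate 3 (adjusted p up to 0.332). Folr2, Il10, Cxcl1 and Mgl2 lost the call without a mean-variance trend and without p47phox-/- replicates 2 and 3 together (adjusted p up to 0.157, 0.109, 0.157 and 0.137).

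Metabolic lists moved by small amounts in p47phox-/-, and markers of other cells of the gut wall moved with them. Oxidative phosphorylation was called higher with 0 of 32 members called (0 higher and 0 lower adjusted over the list alone). The oxidative phosphorylation list had a median log2 fold change of 0.19 (camera adjusted p = 0.00272, adjusted p = 0.817 with an estimated correlation), and lost the call without p47phox-/- replicate 2 (adjusted p = 0.375). Glycolysis and hypoxia response was called lower, with Vegfa the 1 member of 24 that fell (0 higher and 1 lower adjusted over the list alone). The glycolysis list had a median log2 fold change of -0.18 (camera adjusted p = 0.0304, adjusted p = 0.589 with an estimated correlation), and lost the call without WT replicate 1, or p47phox-/- replicate 1 or 3 (adjusted p = 0.0748 to 0.206). Vegfa lost the call in 12 of its alternatives, among them without WT replicate 1, 2 or 3, or p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 2 or 3 (adjusted p up to 0.259). Cholesterol synthesis and efflux was called lower with 0 of 20 members called (0 higher and 0 lower adjusted over the list alone). The cholesterol list had a median log2 fold change of -0.13 (camera adjusted p = 0.0414, adjusted p = 0.589 with an estimated correlation), and lost the call without WT replicate 2, or p47phox-/- replicate 1 or 2 (adjusted p = 0.0877 to 0.291). The unfolded protein response was called lower, with the endoplasmic reticulum chaperones Pdia4 (-0.74) and Creld2 (-0.73) the members that fell of 20 (0 higher and 6 lower adjusted over the list alone). The unfolded protein list had a median log2 fold change of -0.25 (camera adjusted p = 0.0033, adjusted p = 0.584 with an estimated correlation), and lost the call without p47phox-/- replicate 1 (adjusted p = 0.0782). Pdia4 lost the call in 5 of its alternatives, among them without WT replicate 1 or 3, or p47phox-/- replicate 3 (adjusted p up to 0.133). Creld2 lost the call in 13 of its alternatives, among them without WT replicate 1, 2 or 3, or p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 2 or 3 (adjusted p up to 0.147). Fibroblast and smooth muscle markers were called higher, and of the 14 tested, 3 rose, 0 fell and 11 were not called (11 higher and 0 lower adjusted over the list alone), with the matrix gene Sparc at 1374 ± 207 in WT and 2896 ± 429 in p47phox-/-. The fibroblast list had a median log2 fold change of 0.88 (camera adjusted p = 1.48e-11, adjusted p = 0.398 with an estimated correlation). Sparc lost the call in 3 of its alternatives, among them without WT replicate 3 (adjusted p up to 0.0693). T cell and innate lymphoid markers (11 tested, 0 called, 1 higher and 0 lower adjusted over the list alone) and conventional dendritic cell markers (17 tested, with Ccl22 the 1 that rose, 2 higher and 0 lower adjusted over the list alone) were also called higher. The T cell list had a median log2 fold change of 1.22 (camera adjusted p = 0.0268, adjusted p = 0.398 with an estimated correlation), and lost the call without WT replicate 3, or p47phox-/- replicate 1 (adjusted p = 0.0606 to 0.0654). The dendritic cell list had a median log2 fold change of 0.37 (camera adjusted p = 0.0465, adjusted p = 0.589 with an estimated correlation), and lost the call without WT replicate 1 or 3, or p47phox-/- replicate 1 or 2 (adjusted p = 0.108 to 0.176) and under quantile normalization (adjusted p = 0.0785). B and plasma cell markers were not called (14 tested; median log2 fold change -0.25; camera adjusted p = 0.448).

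The size of this comparison depended on which libraries were used. The count of 162 fell to 47 without WT replicate 3, to 61 without p47phox-/- replicate 3, to 101 and 105 without WT replicates 1 and 2, and to 16 without p47phox-/- replicates 2 and 3 together (chosen after seeing the data). It was 101 with the gp91phox-/- libraries out of the fit, 52 without a mean-variance trend and 678 in DESeq2 on recovered reads.

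The gp91phox-/- macrophages differed from WT in more genes, 1016 of 14404 tested (limma, adjusted p under 0.05), of which 364 were higher and 652 lower. Many genes of the B cell lineage were close to 0 in all 3 gp91phox-/- libraries, though not Cd79b and Ighm. Cd79a, a signalling chain of the B cell receptor, had 3639.7 ± 1439 normalized counts in WT and 10.3 ± 4.87 in gp91phox-/- (SD, n = 3), a ratio of 362-fold (95% counting interval 266 to 507) with an adjusted p of 1.69e-07. Some inflammatory and interferon-induced genes rose in the same libraries. The cytokine Il1a rose from 1781 ± 276 to 9406 ± 3895 (log2 fold change 2.33, SE 0.24, adjusted p = 0.000104), Iigp1 from 236 ± 88.2 to 2821 ± 948 (log2 fold change 3.57, SE 0.34, adjusted p = 5.2e-05) and Ptgs2, the inducible prostaglandin synthase, from 4379 ± 589 to 21758 ± 8931 (log2 fold change 2.24, SE 0.27, adjusted p = 0.000335).

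The genes named by rule that fell most in gp91phox-/- were mostly of the B cell lineage. On the log2(normalized count + 1) scale, they included Pax5, the transcription factor of B cell identity (-9.01), Cd79a (-8.36), the IgM receptor Fcmr (-7.94), the complement receptor Cr2 (-7.87), the kinase Blk (-7.85), the sulfotransferase Chst3 (-7.84), the B cell surface protein Ms4a1 (-7.46) and Ly6d (-7.45). Cacna1i, a calcium channel subunit, had 0 reads in the 3 gp91phox-/- libraries and 349.7 ± 75.3 normalized counts in WT, at least 458-fold lower against a floor of 3 reads over the group. Adjusted p for these genes ranged from 1.69e-07 for Cd79a to 3.2e-05 for Ms4a1. Immunoglobulin segments made up 0.851 ± 0.591% of the normalized counts in WT, 0.472 ± 0.237% in p47phox-/- and 0.0354 ± 0.0149% in gp91phox-/- (SD, n = 3), and 68 of the 652 genes that fell were such segments. Of the B and plasma cell markers, 12 of 14 fell (0 higher and 12 lower adjusted over the list alone). The B and plasma cell list had a median log2 fold change of -4.37 (camera adjusted p = 1.91e-20, adjusted p = 0.0943 with an estimated correlation). Residual levels differed among them: Cd79b stayed at 493 ± 42.5 against 1271 ± 349 in WT and Ighm at 3618 ± 707 against 10554 ± 3013.

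Apart from Iigp1, Il1a and Ptgs2, the genes named by rule that rose most in gp91phox-/- were Fcgbp, a mucus protein (5.99), the inducible nitric oxide synthase Nos2 (3.96), Serpina3f (2.75), Btbd11 (2.74), the activin subunit Inhba (2.54), the microRNA host gene Mir155hg (2.46) and the chemokine Ccl12 (2.45). Libraries varied widely for some of them: Nos2 was 289, 1723 and 4513 in the 3 gp91phox-/- libraries and 84.1 ± 14.1 in WT. Of the 20 named genes, 17 stayed called whichever library was left out. Fcgbp lost the call without WT replicate 1 or 3, or gp91phox-/- replicate 1 or 3 (adjusted p = 0.0584 to 0.0843). Btbd11 lost the call without gp91phox-/- replicate 1, 2 or 3 (adjusted p = 0.0609 to 0.11). Inhba lost the call without WT replicate 1, 2 or 3, or gp91phox-/- replicate 2 or 3 (adjusted p = 0.059 to 0.111).

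Inflammatory cytokines and NF-kB targets were called higher as a list in gp91phox-/-, where 17 of 30 rose and 0 fell (20 higher and 0 lower adjusted over the list alone). The inflammatory list had a median log2 fold change of 1.01 (camera adjusted p = 8.16e-14, adjusted p = 0.433 with an estimated correlation). Among them were Nfkbiz (1.58) and Tnfaip3 (1.34), which regulate NF-kB, besides Il1a (2.33) and Ptgs2 (2.24). Of the interferon-induced genes, 13 of 35 rose and 1 fell (14 higher and 1 lower adjusted over the list alone), with the transcription factor Irf1 (1.22) and the GTPases Igtp (1.31) and Gbp5 (1.88) beside Iigp1. The interferon list had a median log2 fold change of 0.39 (camera adjusted p = 6.39e-09, adjusted p = 0.433 with an estimated correlation). In the mature resident macrophage list, of the 30 tested, 3 rose, 1 fell and 26 were not called (9 higher and 1 lower adjusted over the list alone). The mature macrophage list had a median log2 fold change of 0.28 (camera adjusted p = 9.11e-05, adjusted p = 0.546 with an estimated correlation). Il10 (1.35), Timd4 (1.38) and the Fc receptor Fcgr1 (0.65) rose and Gpnmb fell (-1.70). Fcgr1 lost the call in 5 of its alternatives, among them without WT replicate 2 or 3, or gp91phox-/- replicate 2 or 3 (adjusted p up to 0.0996). In the same libraries, B and plasma cell markers had a median log2 fold change of -4.37. Fry called the inflammatory, interferon and B and plasma cell lists (fry adjusted p = 0.0154, 0.0381 and 0.000612). It also called the T cell and dendritic cell lists (0.0157 and 0.0233). It did not call the mature macrophage, oxidative phosphorylation, cell cycle or immediate-early lists (0.131, 0.217, 0.316 and 0.188).

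Further lists moved in gp91phox-/-. Immediate-early and dissociation genes were called higher, and of the 24 tested, 5 rose, 0 fell and 19 were not called (7 higher and 1 lower adjusted over the list alone). Btg2 (1.36), Egr2 (1.08) and Ier3 (0.70) were among those that rose. The immediate-early list had a median log2 fold change of 0.37 (camera adjusted p = 0.000273, adjusted p = 0.616 with an estimated correlation). Cell cycle genes were called higher with Mki67, a marker of dividing cells, the 1 member of 28 called (1.34; 1 higher and 0 lower adjusted over the list alone). The cell cycle list had a median log2 fold change of 0.57 (camera adjusted p = 9.35e-05, adjusted p = 0.616 with an estimated correlation), and lost the call without gp91phox-/- replicate 3 (adjusted p = 0.172). Oxidative phosphorylation was called higher, with Ndufb3, a complex I subunit, the 1 of 32 that rose (0.58; 7 higher and 0 lower adjusted over the list alone). The oxidative phosphorylation list had a median log2 fold change of 0.25 (camera adjusted p = 0.000269, adjusted p = 0.616 with an estimated correlation). Conventional dendritic cell markers were called lower, and of the 17 tested, 0 rose, 4 fell and 13 were not called (1 higher and 5 lower adjusted over the list alone). The dendritic cell list had a median log2 fold change of -0.25 (camera adjusted p = 0.00545, adjusted p = 0.433 with an estimated correlation). Cd209a (-3.17), the cytokine receptor Flt3 (-3.38), the integrin Itgae (-2.75) and the chemokine receptor Ccr7 (-1.47) fell. The MHC class II list was not called (camera adjusted p = 0.777), and 11 of its 16 tested members had positive fold changes. H2-Eb2 (-3.97), H2-Ob (-2.14), H2-DMb2 (-1.52) and H2-Oa (-1.67) fell (1 higher and 4 lower adjusted over the list alone). Many B cell genes were near 0 in the same libraries, and which cells gave these falls was not tested. H2-Oa lost the call in 3 of its alternatives, among them without WT replicate 2, or gp91phox-/- replicate 3 (adjusted p up to 0.0799). Ier3 lost the call in 2 of its alternatives, among them without gp91phox-/- replicate 3 (adjusted p up to 0.0549). Ndufb3 lost the call in 7 of its alternatives, among them without WT replicate 1, 2 or 3, or gp91phox-/- replicate 2 or 3 (adjusted p up to 0.159). Mki67 lost the call without a mean-variance trend (adjusted p = 0.0502). Fibroblast and smooth muscle markers (2 of 14 rose; 5 higher and 0 lower adjusted over the list alone) and colon epithelium markers (0 of 17 called; 0 higher and 0 lower adjusted over the list alone) were called higher, and endothelium markers lower (0 of 12 called; 0 higher and 0 lower adjusted over the list alone). The fibroblast list had a median log2 fold change of 0.31 (camera adjusted p = 0.00997, adjusted p = 0.616 with an estimated correlation). The epithelium list had a median log2 fold change of 0.57 (camera adjusted p = 0.0226, adjusted p = 0.678 with an estimated correlation), and lost the call without WT replicate 2 or 3, or gp91phox-/- replicate 1 (adjusted p = 0.0669 to 0.353). The endothelium list had a median log2 fold change of -0.80 (camera adjusted p = 0.0226, adjusted p = 0.616 with an estimated correlation), and lost the call without WT replicate 1 or 3, or gp91phox-/- replicate 1 (adjusted p = 0.0553 to 0.154).

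**Figure D2:**
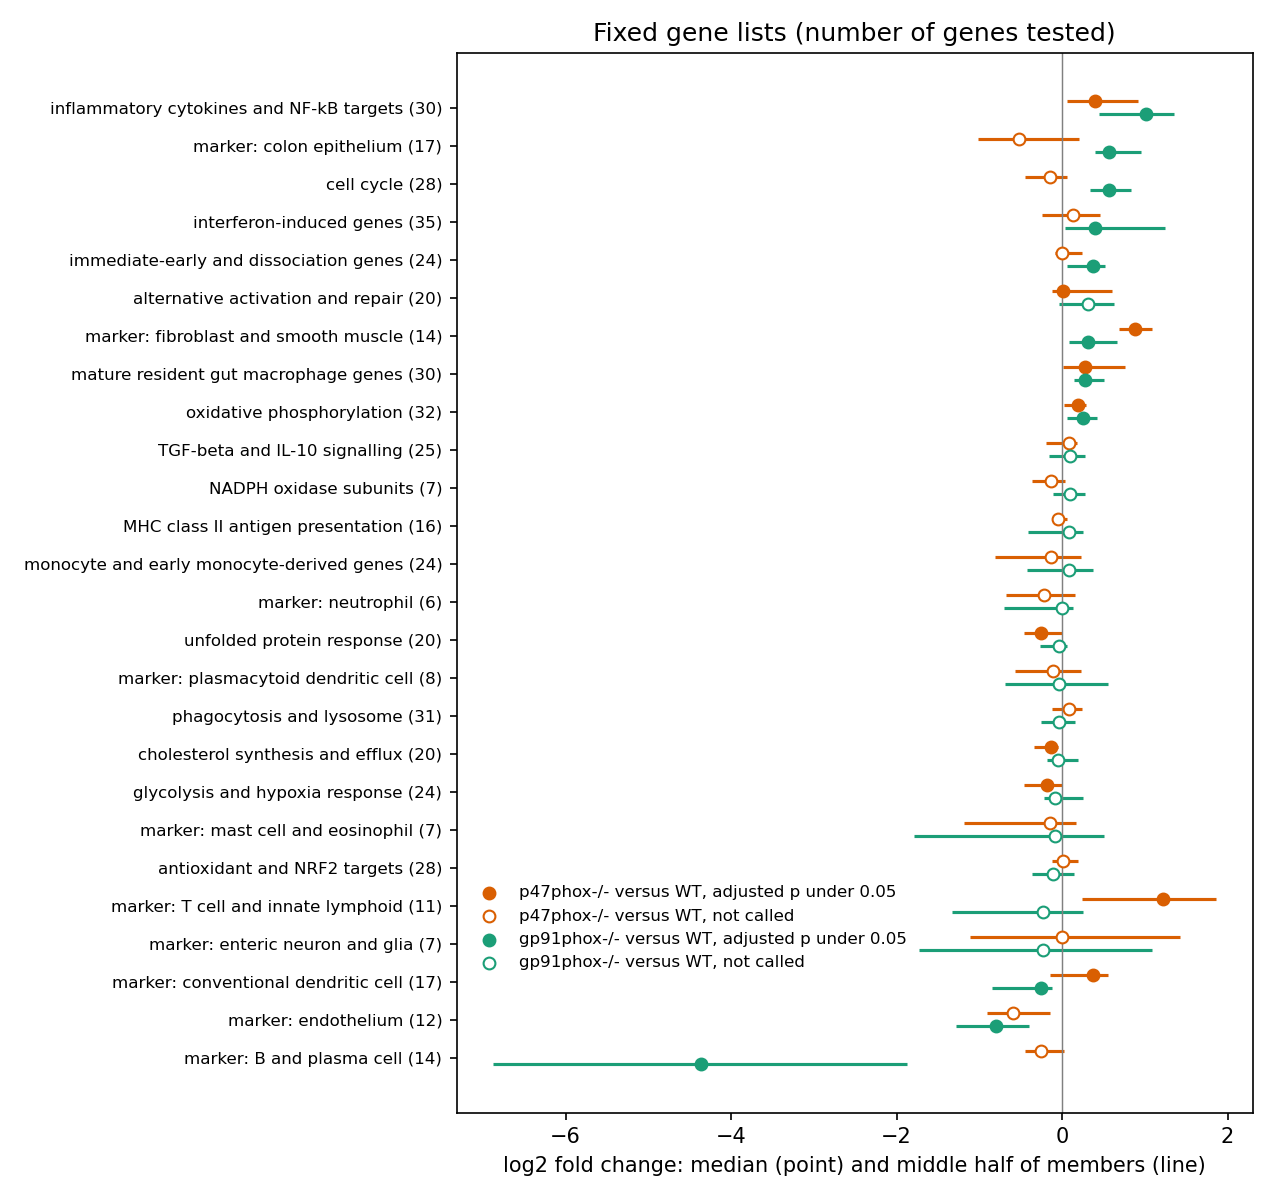
Median log2 fold change (points) and the span from the lower to the upper quartile of members (lines) of each fixed gene list in p47phox-/- versus WT and gp91phox-/- versus WT; filled points are lists with a camera adjusted p under 0.05 at a preset correlation of 0.01, and the number of genes tested stands after each list name. B and plasma cell markers have a median of -4.37 in gp91phox-/- and -0.25 in p47phox-/-, and the inflammatory list 1.01 and 0.40.

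The count of 1016 was 520 without gp91phox-/- replicate 2, 619 without gp91phox-/- replicate 3, 632, 628 and 647 without WT replicates 1, 2 and 3, and 1543 without p47phox-/- replicate 2, which enters the shared estimate of spread. It was 2319 with array weights, 1754 in DESeq2 and 596 without a mean-variance trend, and 932 without immunoglobulin segments and the B and plasma cell list (chosen after seeing the data). That last fit kept other genes near 0 in gp91phox-/-, such as Fcmr, Cr2 and Blk, so 932 is not a count without B cell genes. In the main fit, 176 genes were lower by over 8-fold, and 65 of these were immunoglobulin segments.

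Several fixed lists were called by camera in neither knockout against WT, though single members of most were. They were monocyte and early monocyte-derived genes (1 higher and 3 lower of 24 in p47phox-/-, 1 and 4 in gp91phox-/-, camera adjusted p = 0.0841 and 0.873), antioxidant and NRF2 targets (0 higher and 0 lower of 28 in p47phox-/-, 1 and 2 in gp91phox-/-, camera adjusted p = 0.821 and 0.777), TGF-beta and IL-10 signalling (1 higher and 0 lower of 25 in p47phox-/-, 2 and 1 in gp91phox-/-, camera adjusted p = 0.813 and 0.407), phagocytosis and lysosome (0 higher and 0 lower of 31 in p47phox-/-, 1 and 0 in gp91phox-/-, camera adjusted p = 0.413 and 0.777), and the markers of plasmacytoid dendritic cells (1 higher and 1 lower of 8 in p47phox-/-, 0 and 1 in gp91phox-/-, camera adjusted p = 0.873 and 0.415), mast cells and eosinophils (0 higher and 0 lower of 7 in p47phox-/-, 0 and 1 in gp91phox-/-, camera adjusted p = 0.482 and 0.557), neutrophils (0 higher and 0 lower of 6 in p47phox-/-, 0 and 0 in gp91phox-/-, camera adjusted p = 0.391 and 0.919) and enteric neurons and glia (0 higher and 0 lower of 7 in p47phox-/-, 0 and 1 in gp91phox-/-, camera adjusted p = 0.821 and 0.777). Of these lists, fry called the plasmacytoid dendritic cell markers and the mast cell and eosinophil markers in gp91phox-/- (fry adjusted p = 0.00226 and 0.0154). Of the antioxidant list, the transcription factor Nfe2l2 rose (1.05) and the glutathione genes Gclc (-0.60) and Gstm1 (-0.64) fell in gp91phox-/-. Gclc lost the call without gp91phox-/- replicate 2 (adjusted p = 0.0528). Gstm1 lost the call in 12 of its alternatives, among them without WT replicate 1 or 2, or p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 1, 2 or 3 (adjusted p up to 0.176). The scavenger receptor Msr1 rose (0.85), and Il5ra, a receptor of eosinophils and B cells, was listed at 0 in the 3 gp91phox-/- libraries against 45.1 ± 13.8 in WT (SD, n = 3; adjusted p = 0.000781).

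The direct comparison of gp91phox-/- with p47phox-/- also tests whether the effects of the knockouts differ, since WT cancels. It called 1430 of 14404 genes (limma, adjusted p under 0.05), 572 higher and 858 lower in gp91phox-/-. This balance turned to 863 higher and 798 lower without p47phox-/- replicate 1, and was 714 and 765 with TMM scaling. B cell genes were again among the lowest, such as Pax5 (-8.77), Cd79a (-8.09), Blk (-7.93) and Fcmr (-7.81), none of them called in p47phox-/- against WT. By the naming rule, the genes with the highest fold changes in gp91phox-/- over p47phox-/- were Lrmda (6.30), Ifi208 (5.76), Nos2 (5.21), the intestinal mucin Muc3 (4.88) and the water channel Aqp4 (4.69). Lrmda and Ifi208 were lowest in p47phox-/- replicates 2 and 3, the libraries with reads on fewer genes, but replicate 1 also lay below each gp91phox-/- and WT library. Muc3 was not called in DESeq2 or edgeR. Muc3 lost the call without p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 1, 2 or 3 (adjusted p = 0.0524 to 0.106). Over all alternatives its adjusted p was 0.00272 to 0.111.

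Cx3cr1, the fractalkine receptor and a hallmark of gut macrophages, was 19152 ± 5194 in gp91phox-/-, 4866 ± 749.5 in WT and 2184 ± 2492 in p47phox-/- (SD, n = 3), and differed between the knockouts (log2 fold change 3.74, SE 0.57, adjusted p = 0.00164) without being called in either against WT (adjusted p = 0.161 in p47phox-/- and 0.0622 in gp91phox-/-). Over the alternatives these ranged over 0.000684 to 0.508 and 0.00022 to 0.188, and it was called in each knockout without p47phox-/- replicate 2 and with array weights, among others. The mature resident macrophage list as a whole was not called between the knockouts, and of the 30 tested, 3 rose, 1 fell and 26 were not called (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.749), and Folr2 was lower in gp91phox-/- (-1.23). Of the interferon-induced genes, 12 of 35 were higher and 0 lower in gp91phox-/- (15 higher and 0 lower adjusted over the list alone), among them the chemokine Cxcl10 (1.49). The interferon list had a median log2 fold change of 0.66 (camera adjusted p = 1.17e-06, adjusted p = 0.762 with an estimated correlation). Inflammatory genes split, with 11 higher and 4 lower of 30 (11 higher and 4 lower adjusted over the list alone); Ptgs2 (2.22) and Il1b (1.67) were higher. The inflammatory list had a median log2 fold change of 0.29 (camera adjusted p = 0.00176, adjusted p = 0.762 with an estimated correlation). Cell cycle genes (1 of 28 called higher; 1 higher and 0 lower adjusted over the list alone) and immediate-early genes (3 of 24; 3 higher and 0 lower adjusted over the list alone) were higher as lists. The cell cycle list had a median log2 fold change of 0.75 (camera adjusted p = 2.63e-05, adjusted p = 0.762 with an estimated correlation). The immediate-early list had a median log2 fold change of 0.38 (camera adjusted p = 0.0144, adjusted p = 0.772 with an estimated correlation), and lost the call without p47phox-/- replicate 1, or gp91phox-/- replicate 1 (adjusted p = 0.234 to 0.45) and under quantile normalization (adjusted p = 0.0674).

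Markers of other cells differed between the knockouts in the same libraries. Lower in gp91phox-/- were B and plasma cell markers (12 of 14; 0 higher and 13 lower adjusted over the list alone), T cell and innate lymphoid markers (4 of 11; 0 higher and 4 lower adjusted over the list alone), conventional dendritic cell markers (6 of 17; 0 higher and 9 lower adjusted over the list alone) and fibroblast and smooth muscle markers (3 of 14; 0 higher and 4 lower adjusted over the list alone). The B and plasma cell list had a median log2 fold change of -3.95 (camera adjusted p = 1.02e-16, adjusted p = 0.153 with an estimated correlation). The T cell list had a median log2 fold change of -1.22 (camera adjusted p = 0.00107, adjusted p = 0.187 with an estimated correlation). The dendritic cell list had a median log2 fold change of -0.59 (camera adjusted p = 0.00018, adjusted p = 0.234 with an estimated correlation). The fibroblast list had a median log2 fold change of -0.46 (camera adjusted p = 0.0012, adjusted p = 0.762 with an estimated correlation). The interleukin receptor Il2rb (-3.42), Cd2 (-3.39), Cd209a (-3.54) and the matrix gene Dcn (-0.74) were among them. Dcn lost the call in 7 of its alternatives, among them without p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 1, 2 or 3 (adjusted p up to 0.111). Colon epithelium markers were higher (3 of 17; 3 higher and 0 lower adjusted over the list alone), with Cdh1 at 173 ± 55.6 and 45 ± 5.99. The epithelium list had a median log2 fold change of 0.96 (camera adjusted p = 0.00134, adjusted p = 0.762 with an estimated correlation), and lost the call without p47phox-/- replicate 1 (adjusted p = 0.122). The count of 1430 was 761, 854 and 948 without gp91phox-/- replicates 2, 3 and 1, 441 without p47phox-/- replicates 2 and 3 together (chosen after seeing the data), 898 without a mean-variance trend and 2276 in DESeq2.

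Averaged over both knockouts, 452 genes differed from WT (limma, adjusted p under 0.05), 200 higher and 252 lower. Those that rose most by the naming rule were Fcgbp (5.13), Iigp1 (2.92), Btbd11 (2.37), Serpina3f (2.28), Ccl12 (1.92), Ccl8 (1.87), Mir155hg (1.83), the recombination gene Rad51b (1.78), Il1a (1.74) and Mab21l3 (1.68). Those that fell most were Cacna1i and Nuggc, with 0 and few reads in gp91phox-/-, Lcn2 (-3.54), Fam167a (-2.60), Htra1 (-2.57), Heg1, an endothelial receptor (-2.09), Angptl4 (-2.07), Tmem26 (-2.05), Adam23 (-1.61) and Bspry (-1.49). Fcgbp was not called in p47phox-/- against WT, with normalized counts of 6.71, 44 and 667 there and 3.31, 6.61 and 0 in WT. Of the 452 genes, 50 were called in each against WT, 327 in gp91phox-/- and not in p47phox-/-, and 218 differed between the knockouts. The average was thus carried mainly by gp91phox-/- for many of them.

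Genes called in both knockouts in the same direction numbered 50, of which 35 rose and 15 fell. Examples of the genes that rose in each are Iigp1, Ccl8, Il10 and Timd4, and of those that fell Htra1, Angptl4 and Tmem26. All 7 stayed called in every alternative in gp91phox-/-, but in p47phox-/- all except Timd4 lost the call without a mean-variance trend or without p47phox-/- replicates 2 and 3 together. Htra1 went from 3233 ± 834 in WT to 687 ± 326 in p47phox-/- and 447 ± 84.2 in gp91phox-/- (SD, n = 3; adjusted p = 0.0048 and 0.000138). Another 4 genes were called in opposite directions. With no effect and the same WT libraries shared, simulated data gave a mean of 0.04 genes up in both and 0.02 down. Few genes are called at all without an effect, so an overlap near 0 was given in advance there. Independent lists of the observed sizes would share 2.27 up and 3.26 down, but this leaves out the shared WT libraries, which were too few to split. Neither reference tells how much of the overlap of 50 the shared WT libraries gave. The 50 genes became 19 without WT replicate 3 (11 up and 8 down), 23 without p47phox-/- replicate 3 (14 and 9) and 204 in DESeq2 (126 and 78). Without a mean-variance trend they became 11, and the balance turned to 5 up and 6 down. The fold changes of the knockouts correlated at 0.286 across genes, against 0.499 in simulated data with no effect, their covariance was 0.22 against 0.165, and 59.4% of genes had the same sign in each against 66.7%. Of the lists, 15 of 30 inflammatory genes (19 higher and 2 lower adjusted over the list alone) and 7 of 30 mature macrophage genes (8 higher and 1 lower adjusted over the list alone) rose in the averaged comparison. The inflammatory list had a median log2 fold change of 0.84 (camera adjusted p = 6.92e-16, adjusted p = 0.249 with an estimated correlation). The mature macrophage list had a median log2 fold change of 0.27 (camera adjusted p = 1.46e-06, adjusted p = 0.499 with an estimated correlation). Also called higher were interferon-induced genes (10 of 35 rose), alternative activation, oxidative phosphorylation, cell cycle, immediate-early genes and fibroblast markers, and lower were the unfolded protein response, B and plasma cell markers and endothelium markers. The interferon list had a median log2 fold change of 0.25 (camera adjusted p = 1.46e-06, adjusted p = 0.603 with an estimated correlation). The alternative activation list had a median log2 fold change of 0.29 (camera adjusted p = 0.0401, adjusted p = 0.249 with an estimated correlation), and lost the call without WT replicate 1 or 3, or p47phox-/- replicate 2 or 3, or gp91phox-/- replicate 3 (adjusted p = 0.053 to 0.0958) and under quantile normalization (adjusted p = 0.114). The oxidative phosphorylation list had a median log2 fold change of 0.23 (camera adjusted p = 1.78e-05, adjusted p = 0.68 with an estimated correlation). The cell cycle list had a median log2 fold change of 0.12 (camera adjusted p = 0.0401, adjusted p = 0.819 with an estimated correlation), and lost the call without WT replicate 1 or 3, or p47phox-/- replicate 3, or gp91phox-/- replicate 3 (adjusted p = 0.24 to 0.783) and under quantile normalization (adjusted p = 0.079). The immediate-early list had a median log2 fold change of 0.18 (camera adjusted p = 0.0013, adjusted p = 0.68 with an estimated correlation), and lost the call without WT replicate 2 (adjusted p = 0.157) and under quantile normalization (adjusted p = 0.0898). The fibroblast list had a median log2 fold change of 0.60 (camera adjusted p = 3.61e-08, adjusted p = 0.249 with an estimated correlation). The unfolded protein list had a median log2 fold change of -0.20 (camera adjusted p = 0.0186, adjusted p = 0.603 with an estimated correlation), and lost the call without WT replicate 3, or p47phox-/- replicate 1, or gp91phox-/- replicate 3 (adjusted p = 0.053 to 0.121). The B and plasma cell list had a median log2 fold change of -2.36 (camera adjusted p = 8.04e-16, adjusted p = 0.182 with an estimated correlation). The endothelium list had a median log2 fold change of -0.72 (camera adjusted p = 0.0401, adjusted p = 0.726 with an estimated correlation), and lost the call without WT replicate 1 or 3, or p47phox-/- replicate 2 or 3, or gp91phox-/- replicate 1 or 2 (adjusted p = 0.0514 to 0.316) and with the replicate number as a block (adjusted p = 0.0686). The interferon, cell cycle and immediate-early lists were called in gp91phox-/- but not in p47phox-/- (medians there 0.13, -0.14 and -0.000843, camera adjusted p = 0.204, 0.448 and 0.274). Of the 20 named genes, 15 stayed called whichever library was left out. Fcgbp lost the call without WT replicate 1, 2 or 3, or gp91phox-/- replicate 1 or 3 (adjusted p = 0.0743 to 0.187). Btbd11 lost the call without WT replicate 1, 2 or 3, or p47phox-/- replicate 1 or 3, or gp91phox-/- replicate 1, 2 or 3 (adjusted p = 0.0512 to 0.099). Mir155hg lost the call without WT replicate 1, 2 or 3 (adjusted p = 0.0547 to 0.0956). Mab21l3 lost the call without WT replicate 2 or 3 (adjusted p = 0.0584 to 0.0585). Bspry lost the call without WT replicate 1, 2 or 3, or p47phox-/- replicate 3, or gp91phox-/- replicate 1, 2 or 3 (adjusted p = 0.0638 to 0.222).

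The count of 452 was 173, 199 and 221 without WT replicates 2, 3 and 1, 258 without gp91phox-/- replicate 2, 238 without p47phox-/- replicates 2 and 3 together (chosen after seeing the data), 186 without a mean-variance trend and 1012 in DESeq2.

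**Figure D3:**
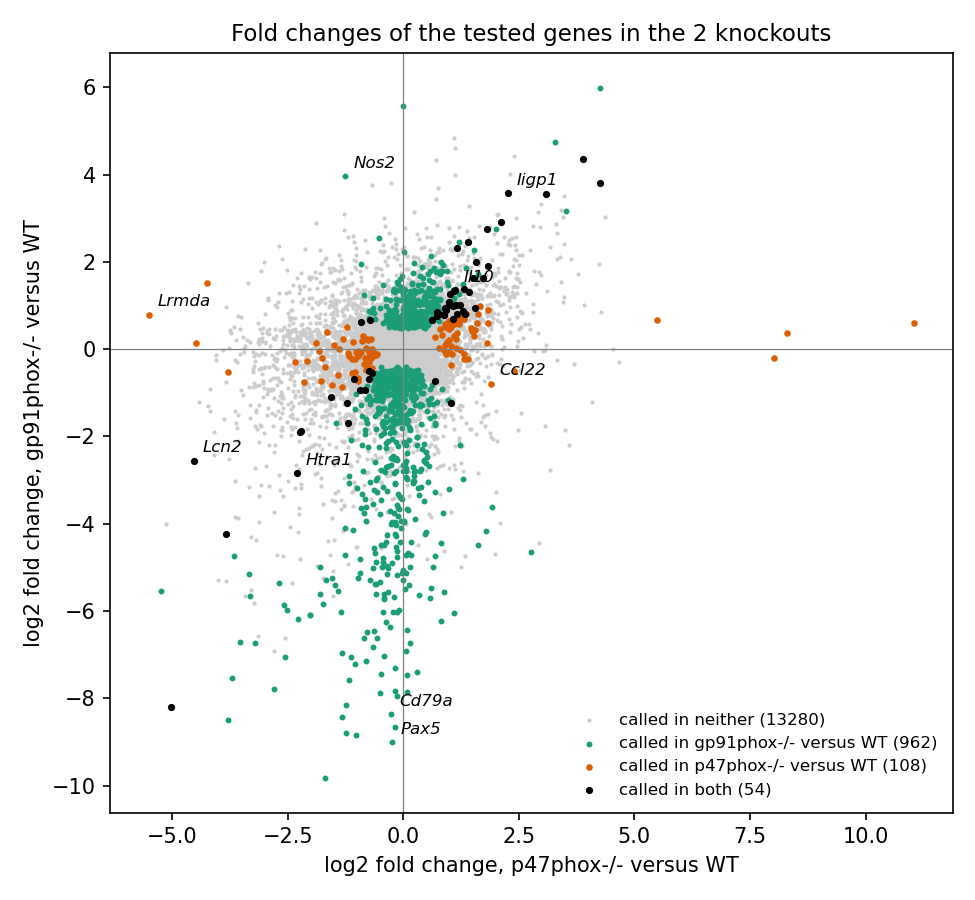
Log2 fold change against WT of each of the 14404 tested genes in p47phox-/- (horizontal) and gp91phox-/- (vertical), coloured by where the gene was called with an adjusted p under 0.05. The 54 genes called in both include Iigp1, Il10 and Htra1, and the B cell genes Pax5 and Cd79a lie near 0 on the horizontal axis.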

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

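The tests of the smallest fall among B cell genes, of marker lists against the B and plasma cell list, of the inflammatory list against the mature macrophage list, of the interferon and inflammatory lists against all other genes and of macrophage maturation were chosen only after the result was seen. Effects of the knockouts differed in 1430 genes by the test of the difference (limma, adjusted p under 0.05), and these included 25 of the 39 genes named in either knockout and 9 of the 16 lists called in either, though 0 lists were called between the knockouts with an estimated correlation (lowest adjusted p = 0.153). Differences are signed log2 fold changes of gp91phox-/- minus those of p47phox-/-, so a positive one can come from a fall in p47phox-/-. This was so for Ncf1 (2.04), Lrmda (6.30), Ifi208 (5.76), Saa3 (3.25), Nrg1 (2.03) and Ccl5 (1.81), called lower in p47phox-/- and not called in gp91phox-/-. Differences were also positive for Iigp1 (1.31), Nos2 (5.21), Inhba (3.06), Ccl12 (1.05), Il1a (1.17) and Ptgs2 (2.22), all called higher in gp91phox-/-. Negative differences were seen for Ccl22 (-2.68), Vasn (-1.25) and Slc45a3 (-1.67), called higher in p47phox-/- and not called in gp91phox-/-. Genes called lower in gp91phox-/- with negative differences were Pax5 (-8.77), Cd79a (-8.09), Fcmr (-7.81), Cr2 (-7.38), Blk (-7.93), Chst3 (-7.65), Ms4a1 (-7.55) and Ly6d (-6.97). Cacna1i had 0 reads in gp91phox-/- and was at least 178-fold lower there than in p47phox-/- against a floor of 3 reads over the group (the fitted -7.12 depends on the pseudocount). Among lists, median differences were 0.29 for inflammatory genes, 0.66 for interferon-induced genes, 0.75 for cell cycle, 0.38 for immediate-early genes, 0.96 for colon epithelium, -1.22 for T cells, -0.59 for dendritic cells, -0.46 for fibroblasts and -3.95 for B and plasma cells. Several of the named genes and lists lost their call against WT with 1 library left out, as the report gives with the libraries.

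Many B cell transcripts, but not Cd79b and Ighm, were near 0 in gp91phox-/- libraries. If fewer B cells were sorted, 7 abundant B cell genes should all have fallen by at least 3 (log2), but the smallest fall was 1.33 (Cd79b), and Ighm fell by 1.53 on the log2 scale, while Cd79a, Ms4a1, Pax5 and Ighd fell by more; Cd79b and Ighm transcripts from other cells could account for this, and the explanation cannot be told apart from a change in the cells. For fewer cells of every other type, 2 of the 9 other marker lists were called lower (dendritic cells, and endothelium, which lost the call without WT replicate 1 or 3, or gp91phox-/- replicate 1), short of most of them, and 2 were called higher (fibroblasts, and colon epithelium, which lost the call without WT replicate 2 or 3, or gp91phox-/- replicate 1). The mean change of a list from WT had a 95% interval over libraries below 0 for dendritic cells (-1.17 to -0.388). This was also so for plasmacytoid dendritic cells (-1.33 to -0.395) and for mast cells and eosinophils (-1.87 to -0.257). It lay above 0 for fibroblasts (0.00254 to 0.793) and spanned 0 for the rest. A sort that removed all other types equally would lower their markers alike, as far as macrophages do not express them. The mean change from WT of each of the 9 lists lay above that of the B and plasma cell list, by 3.43 to 5.32 (log2). The lowest end of the 95% intervals over libraries was 1.99. The B and plasma cell list was the one that had fallen most, so the other lists were bound to lie above it. Members with low values in WT could not fall as far. Markers that macrophages also express could not either, and Lyve1, an endothelium marker, is also in the mature macrophage list. The comparison therefore cannot decide whether all other types were lost equally. Loss of B cells alone from the sort is not covered by this comparison. An effect of the genotype stays open, and was not tested apart from these.

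In gp91phox-/-, 13 of 35 interferon-induced genes rose and 1 fell, and 17 of 30 inflammatory genes rose and 0 fell; both lists were called higher, though not with an estimated correlation (adjusted p = 0.433 each). Less B cell RNA would raise the share of all other RNA alike, and the median of the interferon list lay 0.113 above that of the mature macrophage list, within the bound of 0.2 set for it (bootstrap interval -0.0713 to 0.853), but that list was itself raised, so the comparison cannot support a shift of all RNA. The inflammatory list lay 0.734 above it, but the interval over libraries of the difference in means spans 0 (-0.103 to 1.38). All other genes had a median of 0.0124. The interferon list lay 0.382 above them (95% interval over libraries of the difference in means 0.254 to 1.14) and the inflammatory list 1.002 (0.419 to 1.6). Camera, which had flagged both lists, also compares a list with other genes, so this comparison repeats that result. The values were scaled by size factors too, so a shift of all other RNA may not show in them. The comparison shows only that both lists rose beyond the other genes, and no conclusion on such a shift is drawn. A rise of macrophage genes alone is not covered by this comparison either. Against the mature macrophage list, the interval over libraries of the interferon list also spans 0 (-0.329 to 0.973). Stress during dissociation stays a candidate explanation, since the immediate-early list had a median of 0.370 and was called, though not with an estimated correlation (adjusted p = 0.616), and so does genotype.

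Large shifts of single genes were seen in p47phox-/-. For a donor-strain chromosome around Ncf1, calls near it had an odds ratio of 0.833 (95% interval 0.0994 to 3.1, two-sided Fisher's exact test p = 1, 2 of 212 genes called, with Eln, within 1 Mb of Ncf1, among them), so an excess of a few-fold stays possible and this cannot be told; the other 157 called genes with a position lie outside this window. For donor segments elsewhere, 36 pairs of called genes lay within 1 Mb against a median of 22 in 1000 random draws (95% range 13 to 35; 21 draws were as high), which meets the bound set beforehand, but gp91phox-/- showed the same kind of excess (1074 against 821) and the pairs include chemokine neighbours such as Ccl2, Ccl12 and Ccl8, so clusters of related genes could also give it. A shift along maturation, to explain Cx3cr1 (3.74 between the knockouts), would need the mature macrophage list to move with it, but its median difference was 0.0591 (upper quartile 0.29).

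With 3 libraries against 3, only 10 splits exist, too few for a share under 0.05: 1 of 10, the real one, reached 162 called genes for p47phox-/- versus WT (highest other 2), 1 of 10 reached 1016 for gp91phox-/- versus WT (highest other 0) and 1 of 10 reached 1430 for gp91phox-/- versus p47phox-/- (highest other 0). For both knockouts versus WT, 3 of 100 splits drawn from 840 reached 452. Most of the others mix genotypes within groups, which widens the spread, so this share says little about chance. The highest other called 1514 genes and is the real grouping with gp91phox-/- set against the rest, which points to a structure set by those libraries.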

How the results depend on the processing

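The fits without p47phox-/- replicates 2 and 3, and without immunoglobulin segments and the B and plasma cell list, were chosen only after the result was seen. All 254 results for single genes kept their direction in every alternative, and 118 kept their side of the threshold in every one of those run for them. Of genes named by rule, 0 of 20 in p47phox-/-, 16 of 20 in gp91phox-/-, 8 of 10 between the knockouts and 14 of 20 for both knockouts stayed called in every alternative. Counts are given in the order p47phox-/-, gp91phox-/-, gp91phox-/- versus p47phox-/-, both knockouts, and genes shared in the same direction (162, 1016, 1430, 452 and 50). Without a mean-variance trend they were 52, 596, 898, 186 and 11. In DESeq2 they were 678, 1754, 2276, 1012 and 204, and in edgeR 133, 973, 1315 and 478 for the first 4. Genes called in both limma and edgeR numbered 131, 920, 1235 and 430, and in both limma and DESeq2 162, 1009, 1419 and 449. With only the groups compared, p47phox-/- versus WT had 101. Array weights gave 2319 for gp91phox-/- versus WT. At an adjusted p under 0.1 the shared genes were 133. Without p47phox-/- replicates 2 and 3, where replicate 1 is assumed to vary like the other groups, counts were 16 for p47phox-/- versus WT, 441 between the knockouts and 238 for both.

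With each library left out in turn, counts ranged over 47 to 235, 520 to 1543, 761 to 1661, 173 to 619 and 19 to 70. The shared genes were 19 without WT replicate 3 and 23 without p47phox-/- replicate 3. Lists called by camera (10, 11, 9 and 11) ranged over 6 to 11, 9 to 12, 7 to 11 and 7 to 10, and were 0, 0, 0 and 0 with an estimated correlation. With the stricter filter they were 7, 11, 10 and 9. Single lists were followed in 12 settings, which were TMM, quantile scaling, the replicate block and each library left out. In all of these, 2 of 10, 8 of 11, 7 of 9 and 6 of 11 stayed called. With the replicate number as a block the counts were 127, 877, 1238 and 371, within 1.5 times; the deviations of libraries that share a number correlated at -0.0398 to 0.0763, so the numbers were not read as pairs. Without immunoglobulin segments and the B and plasma cell list, the counts were 192, 932, 1394 and 428, with other B cell genes such as Fcmr, Cr2 and Blk kept. TMM and quantile scaling moved the median of all genes by under 0.1 (log2). Fewer libraries lower the power of the leave-one-out fits; apart from that, the cause was not tested. Depth limits genes near 0, for which ratios carry counting intervals.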

Other observations

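The genes in this part were chosen only after the result was seen, so their values are descriptions and carry no weight as tests. Gm42031, a gene model on chromosome 8 (85125923 to 85131814), was 3525, 2766 and 1701 in the p47phox-/- libraries, 0, 0.734 and 0 in WT and 0, 0.603 and 2.68 in gp91phox-/-. Thbs1, which encodes a matrix glycoprotein, fell from 154780 ± 16790.2 in WT to 46049 ± 8270.4 in p47phox-/- (SD, n = 3; log2 fold change -1.76, adjusted p = 0.00301) and was 136949 ± 30763 in gp91phox-/-. Siglech, a sialic acid-binding lectin, rose in p47phox-/- from 291 ± 47.9 to 894 ± 211 (log2 fold change 1.60, adjusted p = 0.00432). How reads that match more than 1 gene were handled is not given in the sources used here. Whether Iigp1, Gm4951 and F830016B08Rik share reads was not tested. All 3 genes were called higher in p47phox-/- (2.26, 2.10 and 3.08) but lost the call without a mean-variance trend. Siglech and Thbs1 lost the call in p47phox-/- without p47phox-/- replicates 2 and 3 together (adjusted p = 0.109 and 0.079).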
